A study of Mus musculus with 6 samples.

How the data were processed

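RNA was taken from hematopoietic stem cells of wild-type mouse bone marrow, sorted as F4/80 negative or F4/80 positive, with 3 libraries per group from 2000 to 5000 cells each. Per the labels' protocols, total RNA was extracted with a micro-scale column kit and libraries were prepared with a SMARTer stranded kit. The submitters' processing notes name HISAT2 2.0.5, DESeq2 and the GRCm39 (mm39) build, without saying what each was used for. The read counter, the annotation release, any filter and the use of strand are not given in the sources used here. Genes that share reads with paralogs, such as the globin, Gbp and H2 families, and overlapping or antisense genes are therefore uncertain in their split of reads.

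The authors deposited 1 table for the whole series with 23413 genes, and each of them has at least 2 counts over the 6 libraries. Its raw counts per gene, as deposited by the authors, are whole numbers and were the only values tested. The authors also deposited a normalized signal per library, which equals the count divided by 1 size factor per library, and the authors' group means of that signal. The FPKM values deposited by the authors use the gene length of the table and a library size that differs from the column total by 1 constant per library. The authors' log2 fold changes and the authors' p-values come from their own comparison of positive with negative libraries. In the authors' deposited table, 1697 genes were higher and 1921 lower at an adjusted p below 0.05. The adjusted p in the authors' deposited table was 1 for 6817 genes. No row lacked a gene, and no value column belonged to other samples. Gene symbols, biotypes and coordinates were taken from the table itself. The annotation at hand is of another build, GRCm38. It held 22445 of the identifiers (95.9%) and none of its coordinates were used.

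Total counts were 20103661, 18649394 and 18863378 in F4/80 negative replicates 1 to 3, and 18969755, 18637526 and 21042379 in F4/80 positive replicates 1 to 3. Genes with any count numbered 19390 to 20083 in negative and 18758 to 19292 in positive libraries. Mitochondrial genes took 0.65% to 0.783% of counts in negative and 0.525% to 0.619% in positive libraries. Both measures part the groups without overlap, and whether RNA quality differed between the groups was not tested. A floor of 3 counts corresponds to between 0.147 and 0.167 CPM, and this covers counting error only, because reads were not counted as unique molecules. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom between 11.7 and 24.9, so none was treated as 1 library deposited under more than 1 name. This check does not tell repeat preparations of 1 sample from separate samples.

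Counts were analysed in R 4.3.3 with edgeR 4.0.16, using filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors, and the quasi-likelihood test (glmQLFit and glmQLFTest) of positive against negative libraries without covariates. This kept 14451 genes. A call is a Benjamini-Hochberg adjusted p below 0.05 over these genes. Levels are CPM with TMM factors, log2 CPM use a prior count of 2, and the standard error of a log2 fold change is the one implied by the F test. Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, for the 34 of 35 lists with at least 5 tested members, and with adjustment over lists. The groups, lists, tests, alternative settings and the rule for named genes were set before the data were examined.

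By that rule the text names Adgre1 and Kit, up to 12 higher and 12 lower genes with the largest fold change, up to 6 called members per list by p, and fixed marker genes whatever their test. Some genes that the rule names are not reported here. The genes with the largest fold change needed an average log2 CPM of at least 2, a gene symbol that is no predicted model or pseudogene, and no overlap of the groups. Of the 2967 called genes 99.3% had no overlap, against 40.6% of all tested genes and 10% by chance.

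The libraries share replicate numbers across the groups. Deviations from the group means in log2 CPM correlated between same-numbered libraries by 0.214 to 0.284, and by -0.2 to -0.071 between libraries of other numbers in the other group. Deviations from the mean cancel within each group, so higher values for same-numbered pairs force lower values for the others. The second range is thus no separate evidence. Every same-numbered pair exceeded 0.1, the limit set for the pairing, and the labels name the libraries by the numbers 4, 5 and 7 in both groups. The pairing thus comes from the numbers and this check, and the blocked value is given where it changes the call of a named gene or list or moves a count of calls by over 1.5 times.

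The edgeR step was tested on simulated counts for the 14451 genes with 200 changed genes. Without a block, on counts simulated without replicate effects, it recovered 36% of 1.5-fold, 62% of 2-fold, 88% of 4-fold and 90% of 8-fold changes. It made 10 false calls (6.76%). The replicate block was tried on other simulated counts, in which libraries of the same number shared an effect. There it recovered 20%, 62%, 82% and 92% and made 17 false calls (11.7%). The fit without a block was not tried on counts with such shared effects, so its false calls there are unknown. Camera called the 1 shifted list and 0 of 33 unchanged lists in simulated counts, where genes vary independently.

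Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, total counts alone, scaling without hemoglobin, mitochondrial and ribosomal protein genes, no filter (at least 1 count), at least 50 counts in at least 3 libraries, protein-coding genes only, the replicate block, each library left out, and for lists an estimated correlation and fry. Chosen only after seeing the data were the fit without both libraries numbered 3, camera with the block and an estimated correlation, and the replicate block with a gene length correction (a lowess trend with span 0.3). Settings for tables of normalized values were not run, since counts exist.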

Results

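Messenger RNA was measured in hematopoietic stem cells sorted from the bone marrow of wild-type mice into cells negative and cells positive for F4/80, a surface protein encoded by Adgre1 and used as a marker of macrophages. Each group had 3 libraries, made from 2000 to 5000 sorted cells each. The deposited counts summed to between 18637526 and 21042379 per library, and 14451 of the 23413 genes in the table passed the filter on low counts. The series title concerns trogocytosis, the transfer of membrane from one cell to another, linked to the receptor c-Kit. The design asks how the transcriptome of stem cells carrying F4/80 differs from that of stem cells without it.

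F4/80 positive libraries held more macrophage transcripts and more cell cycle transcripts than F4/80 negative libraries, and fewer transcripts of genes that mark long-term stem cells and of interferon response genes. Of 27 tested macrophage genes, 21 rose and 0 fell, with a median of 5.86-fold. In the G2/M list, which holds genes of mitosis, 48 of 52 rose and 0 fell. In the stem cell identity list 21 of 33 fell and 2 rose, and in the interferon response list 23 of 33 fell and 0 rose. Across all tested genes 1395 were higher and 1572 lower in the positive libraries, by edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p below 0.05. More than 2-fold changes were found for 283 of the higher and 817 of the lower genes.

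Adgre1 itself (ENSMUSG00000004730, GRCm39 chromosome 17, 57665691 to 57790527, plus strand, protein-coding) measured 32.1 ± 9.46 CPM (SD, n = 3) in the positive and 2.30 ± 0.782 CPM (SD, n = 3) in the negative libraries. This is a log2 fold change of 3.79 with a standard error of 0.32, higher in all 3 positive libraries (edgeR quasi-likelihood adjusted p = 0.000659). The exact two-sided permutation test of its log2 CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow. Kit (ENSMUSG00000005672, GRCm39 chromosome 5, 75735576 to 75817382, plus strand), which encodes the c-Kit receptor, measured 1444 ± 206 CPM (SD, n = 3) in the positive and 1732 ± 219 CPM (SD, n = 3) in the negative libraries. Its log2 fold change of -0.26 (SE 0.12) did not pass the edgeR test (adjusted p = 0.159), and with the replicate number as a block it did (log2 fold change -0.26, SE 0.05, edgeR adjusted p = 0.00415, the lowest over its alternatives, with 0.441 the highest).

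Among macrophage genes, Vcam1, an adhesion molecule of marrow macrophages and stroma, rose 16.0-fold, from 10.3 ± 3.70 to 166 ± 57.0 CPM (SD, n = 3 per group). The genes of complement component C1q rose together, C1qa by 14.3-fold, C1qb by 13.8-fold and C1qc by 12.3-fold. Mrc1, the mannose receptor, rose 13.2-fold and Cd5l, a protein secreted by macrophages, 11.8-fold. Csf1r, the receptor for macrophage colony-stimulating factor, rose 5.86-fold (9.53-fold without negative replicate 2) and Cd68, a lysosomal glycoprotein, 2.86-fold. Fcgr1 rose 6.77-fold and Mertk 4.25-fold, from levels below 3 CPM, and both calls were lost when single libraries were left out. Fcgr1 lost its call without negative replicate 3, positive replicate 1 or positive replicate 2, and Mertk without any library except negative replicate 3, with adjusted p over the alternatives, DESeq2 and limma-voom included, up to 0.0769 and 0.119. Mertk also lost it with no composition factor, and its fold was 10.4 without negative replicate 3. Lyz2, the lysozyme of myeloid cells, measured 473 ± 38.8 CPM in positive and 487 ± 39.5 CPM in negative libraries (SD, n = 3), a log2 fold change of -0.04 (SE 0.09). Adjusted over the list alone, 22 macrophage genes were higher. The list was called by camera (adjusted p = 7.64e-32), with adjusted p = 0.248 with an estimated correlation.

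**Figure D1:**
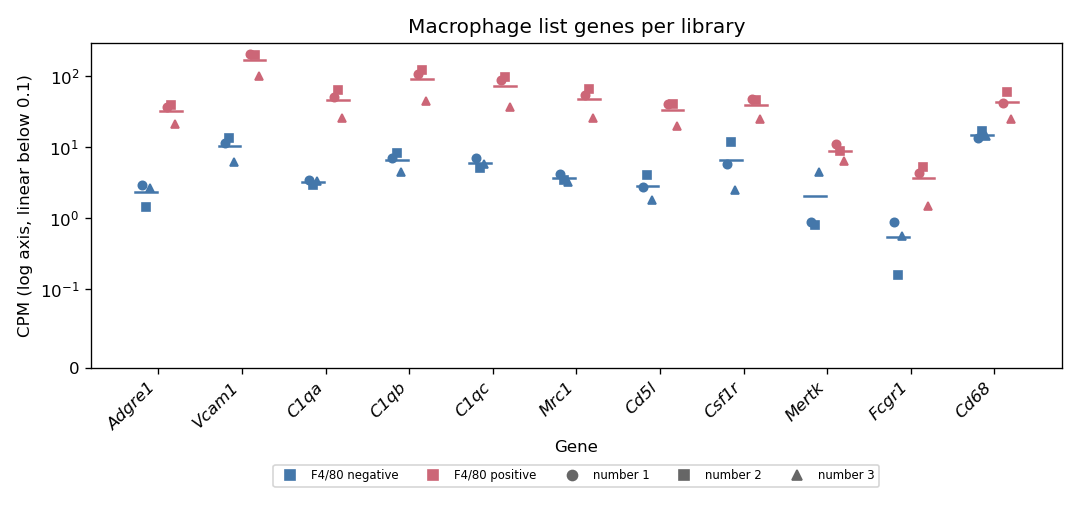
CPM of 11 macrophage list genes in each library, on a log axis that is linear below 0.1 CPM. Colours mark the groups, symbols the replicate numbers and horizontal lines the group means of 3 libraries. Adgre1 averages 32.1 CPM in positive and 2.30 CPM in negative libraries, and Vcam1 166 and 10.3 CPM.

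Of 23 iron and heme genes, 7 rose and 0 fell (7 adjusted over the list alone). Hmox1, the heme-degrading enzyme heme oxygenase 1 (GRCm39 chromosome 8, 75820249 to 75827217), rose 8.09-fold, from 17.6 ± 1.91 to 142 ± 26.7 CPM (SD, n = 3 per group). Slc11a1, a metal transporter of phagosomes, rose 9.04-fold, Slc40a1, the iron exporter ferroportin, 4.31-fold, and Cd163, the hemoglobin scavenger receptor, 3.24-fold. Hmox1, Slc40a1 and Cd163, 3 of the 7 higher genes, are also in the macrophage list. The median log2 fold change of this list was only 0.05, and it was -0.03 with no composition factor. Its camera call (adjusted p = 0.000106) went with adjusted p = 0.313 with an estimated correlation. Of 44 genes of phagocytosis and membrane uptake, 14 rose and 2 fell (16 and 5 adjusted over the list alone). Timd4, a receptor for phosphatidylserine, rose 23.3-fold from 0.304 CPM, Axl, a receptor for apoptotic cells, 2.89-fold, and Syk, a kinase downstream of Fc receptors, 1.44-fold. Of the 14 higher uptake genes 4 are also in the macrophage list, Timd4, Axl, Mertk and Fcgr1. Gas6, the ligand of Axl, fell by 1.99 on the log2 scale. The camera adjusted p was 0.00281, and adjusted p = 0.248 with an estimated correlation.

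Stem cell identity genes fell unevenly. Procr, which encodes the endothelial protein C receptor used to isolate stem cells, measured 17.6 ± 4.04 CPM in positive and 97.7 ± 24.7 CPM in negative libraries (SD, n = 3), and was 5.57-fold lower. Ly6a, which encodes Sca-1, was 4.34-fold lower, Fgd5 4.11-fold, Mllt3 3.58-fold, Hlf 2.89-fold and Mecom 2.54-fold. Slamf1, which encodes CD150, measured 51.7 ± 6.44 and 50.9 ± 5.22 CPM (SD, n = 3), a log2 fold change of 0.02 (SE 0.13). Cd34 had a log2 fold change of 0.03 (SE 0.08). Adjusted over the list alone, 21 identity genes were lower and 3 higher. The camera adjusted p was 1.68e-12, and adjusted p = 0.292 with an estimated correlation. In the list of quiescence regulators 8 of 23 fell and 3 rose (8 and 4 adjusted over the list alone). Cdkn1c, the cell cycle inhibitor p57, was 4.27-fold lower, Txnip 2.06-fold and Gfi1 8.97-fold, while the inhibitor Cdkn2c rose from 24.4 to 48.8 CPM. This list had a camera adjusted p of 0.0109, and adjusted p = 0.414 with an estimated correlation, and its call was also lost with limma-voom. Among multipotent progenitor genes 2 rose and 1 fell of 17. Notch1 was 2.60-fold lower. Flt3 had a log2 fold change of -0.46 (SE 0.25), which passed only with the replicate block (edgeR adjusted p = 0.225 without and 0.00801 with it, and up to 0.491 over the alternatives).

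Cell cycle genes rose by a smaller factor but almost throughout. Of 42 G1/S genes, 38 rose and 0 fell (41 adjusted over the list alone), with a median of 1.56-fold. Both subunit genes of ribonucleotide reductase were among them, Rrm1 with 1.69-fold and Rrm2 with 1.87-fold. The 48 higher G2/M genes (50 adjusted over the list alone) had as examples Aurkb, Hmmr, Tpx2 and Ube2c, which rose 2.27-fold, 2.19-fold, 2.20-fold and 2.47-fold, and the median of the list was 2.05-fold. Mki67, the proliferation marker, rose from 115 ± 33.9 to 239 ± 10.6 CPM (SD, n = 3 per group). Cdk6 rose 1.69-fold and lost its call without negative replicate 2, negative replicate 3, positive replicate 1 or positive replicate 3, with adjusted p over the alternatives from 0.000544 (DESeq2) to 0.171 (edgeR without both libraries numbered 3). Camera gave adjusted p = 2.81e-29 for G1/S and 1.32e-64 for G2/M, and adjusted p = 0.248 for both with an estimated correlation.

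**Figure D2:**
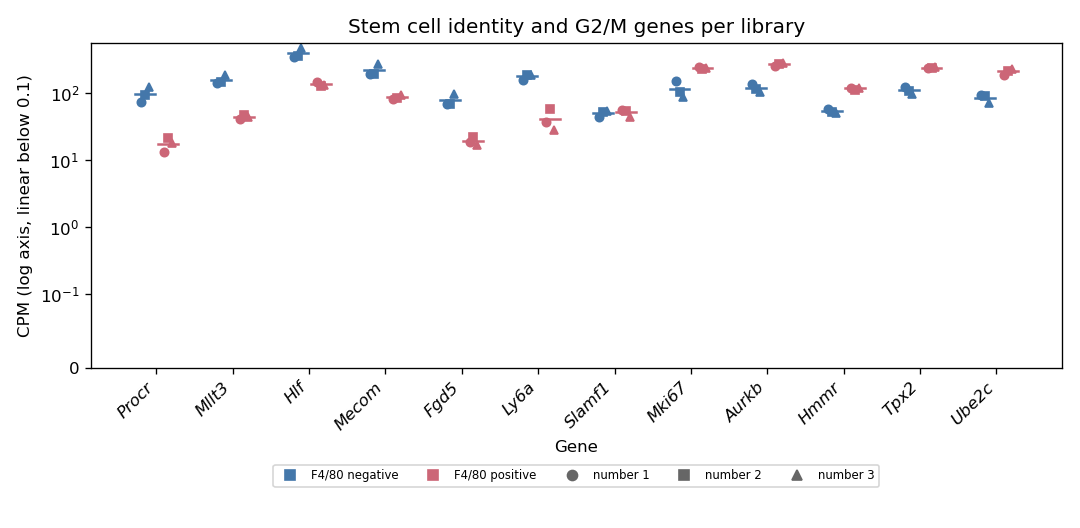
CPM of 6 tested stem cell identity genes and Slamf1, and of 5 G2/M genes, in each library, on a log axis that is linear below 0.1 CPM. Colours mark the groups, symbols the replicate numbers and lines the group means of 3 libraries. Procr averages 17.6 CPM in positive and 97.7 CPM in negative libraries, and Mki67 239 and 115 CPM.

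Of 20 megakaryocyte and platelet genes 9 rose and 1 fell (9 and 1 adjusted over the list alone). Pf4, platelet factor 4, rose 6.52-fold, from 48.0 ± 19.0 to 313 ± 94.4 CPM (SD, n = 3 per group). The thrombin receptor family gene F2rl2 rose 4.29-fold, Itga2b, which encodes CD41, 3.13-fold, and Treml1 2.97-fold. Vwf, von Willebrand factor, had a log2 fold change of 0.01 (SE 0.30). The camera adjusted p was 3.07e-07, and adjusted p = 0.248 with an estimated correlation. Of 6 tested mast cell, basophil and eosinophil genes 3 rose and 0 fell (5 adjusted over the list alone), among them Cpa3, a mast cell protease, by 2.77-fold. This list had a camera adjusted p of 0.000973, and adjusted p = 0.248 with an estimated correlation. Of 22 erythroid genes 1 rose and 2 fell. The gene that rose was Gata1, a transcription factor shared by erythroid and megakaryocyte cells, with 2.29-fold. Hbb-bs, an adult beta globin gene, had a log2 fold change of 1.01 and did not pass the edgeR test (adjusted p = 0.113). It passed in edgeR with the replicate block (adjusted p = 0.0202) and without positive replicate 2 (adjusted p = 0.0293), with adjusted p up to 0.392 over the alternatives. Hbb-bt, another beta globin gene, was among the 2 erythroid genes that fell, from 12.9 ± 2.09 to 7.01 ± 0.733 CPM (SD, n = 3 per group). Its log2 fold change was -0.88 (edgeR adjusted p = 0.0158). The Hbb-bt call was lost without positive replicate 2 and without both libraries numbered 3. The split of reads between these globin genes is uncertain.

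Of 15 monocyte genes 2 rose, among them Csf1r, which is also in the macrophage list. Of 15 neutrophil genes 1 rose and 2 fell, and S100a8 measured 22.2 ± 21.6 and 31.3 ± 32.5 CPM (SD, n = 3), a spread as wide as its mean. Of 17 granulocyte-monocyte progenitor genes 4 rose and 3 fell, of 7 dendritic cell genes 2 fell and 0 rose, and of 11 endothelial and stromal genes 2 rose and 1 fell. Of 5 T and NK cell genes 1 rose and 2 fell. Cd3e was not tested, with 4 to 13 counts in the negative libraries and 0 in the positive libraries, which allows up to 0.167 CPM. Of 13 B cell genes 1 fell, Il7r, while the median log2 fold change was -1.80 and the highest of the 13 was -0.13. The camera adjusted p of the B cell list was 0.0325, and adjusted p = 0.827 with an estimated correlation. That call was also lost with limma-voom, with fry, with no composition factor, and without negative replicate 1, negative replicate 2 or positive replicate 3 (adjusted p up to 0.228). Cd79a measured 10.1, 12.2 and 1.13 CPM in negative replicates 1 to 3, and 1.34, 2.34 and 0 CPM in positive replicates 1 to 3. With a log2 fold change of -2.68 (SE 1.05), Cd79a did not pass the edgeR test (adjusted p = 0.103). It passed in edgeR with the replicate block (adjusted p = 0.00222) and without both libraries numbered 3 (adjusted p = 0.0184), with adjusted p up to 0.26 over the alternatives.

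Of the 33 interferon response genes 23 fell, among them Ifitm1, which was 3.05-fold lower, Ifi44 3.07-fold, Gbp2 1.67-fold and the nucleic acid sensor Zbp1 2.23-fold. Adjusted over the list alone, 28 were lower and 1 higher. The camera adjusted p was 6.87e-13, and adjusted p = 0.292 with an estimated correlation. Of 12 MHC class II genes 5 fell and 0 rose (5 and 1 adjusted over the list alone). Cd74, the invariant chain, measured 56.7 ± 19.6 CPM in positive and 193 ± 25.8 CPM in negative libraries (SD, n = 3), and H2-Aa was 3.53-fold lower. Camera gave this list an adjusted p of 0.0115, and adjusted p = 0.42 with an estimated correlation. The preset call ended without positive replicate 1 or positive replicate 3, with adjusted p up to 0.113 when single libraries were left out. Of 27 inflammatory and NF-kB genes 9 fell and 1 rose (13 and 2 adjusted over the list alone), with Traf1 3.94-fold and Tnfrsf1b 1.69-fold lower. Camera gave this list an adjusted p of 0.00349, and adjusted p = 0.378 with an estimated correlation. Of 16 MHC class I genes 4 rose and 3 fell.

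Genes of niche retention, adhesion and mobilization fell more often than they rose, with 12 lower and 2 higher of 34 (15 and 5 adjusted over the list alone). Robo4, a guidance receptor of stem cells and endothelium, was 2.73-fold lower, and the adhesion molecule gene Icam1 was 1.82-fold lower. Cxcr4 had a log2 fold change of -0.03 (SE 0.18) and Itga4 of -0.06 (SE 0.12). Camera gave an adjusted p of 0.00182, and adjusted p = 0.248 with an estimated correlation. Of 41 genes of KIT receptor signalling 6 fell and 4 rose. Pik3r1, a regulatory subunit of PI3 kinase, was 1.99-fold lower. Cd47, a signal against phagocytosis, had a log2 fold change of 0.15 (SE 0.10), and Sirpa, its receptor, of 0.43 (SE 0.14), with edgeR adjusted p = 0.0591. Sirpa passed with the replicate block (edgeR adjusted p = 0.0202), with DESeq2 (adjusted p = 0.0166), and in edgeR with no low-count filter (0.047), without positive replicate 3 (0.0167) and without both libraries numbered 3 (0.0418), with adjusted p up to 0.177 over the alternatives.

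Nuclear-encoded genes of oxidative phosphorylation rose by a small factor, 36 of 52 with 0 lower (47 adjusted over the list alone) and a median of 1.28-fold. Ndufa4 rose 1.46-fold and Cox6a1 1.39-fold. The camera adjusted p was 2.19e-13, and adjusted p = 0.452 with an estimated correlation. Of the 15 mitochondrially encoded genes 2 fell and 0 rose. Ribosomal protein genes had 1 higher of 55, Rpl27, with a camera adjusted p of 0.0391 and adjusted p = 0.906 with an estimated correlation. The list call was also lost with fry, no composition factor or the strict filter, and with the replicate block and gene length correction. It was further lost without negative replicate 1, negative replicate 3, positive replicate 2 or positive replicate 3, and without both libraries numbered 3. Rpl27 lost its call with no composition factor and without any library except negative replicate 2, with adjusted p over the alternatives from 0.00858 (DESeq2) to 0.218 (edgeR without both libraries numbered 3). Glycolysis genes had 3 higher and 5 lower of 23 entries, with Aldoa listed under 2 identifiers, cholesterol biosynthesis 1 higher and 2 lower of 23, lysosome and autophagy 1 higher and 5 lower of 39, oxidative stress defence 3 higher and 2 lower of 24, and heat shock and unfolded protein response 4 higher and 1 lower of 27. Nuclear and non-coding RNA had 2 lower of 8, immediate early genes 3 lower of 19, and the 4 tested sex-linked genes none past the threshold.

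**Figure D3:**
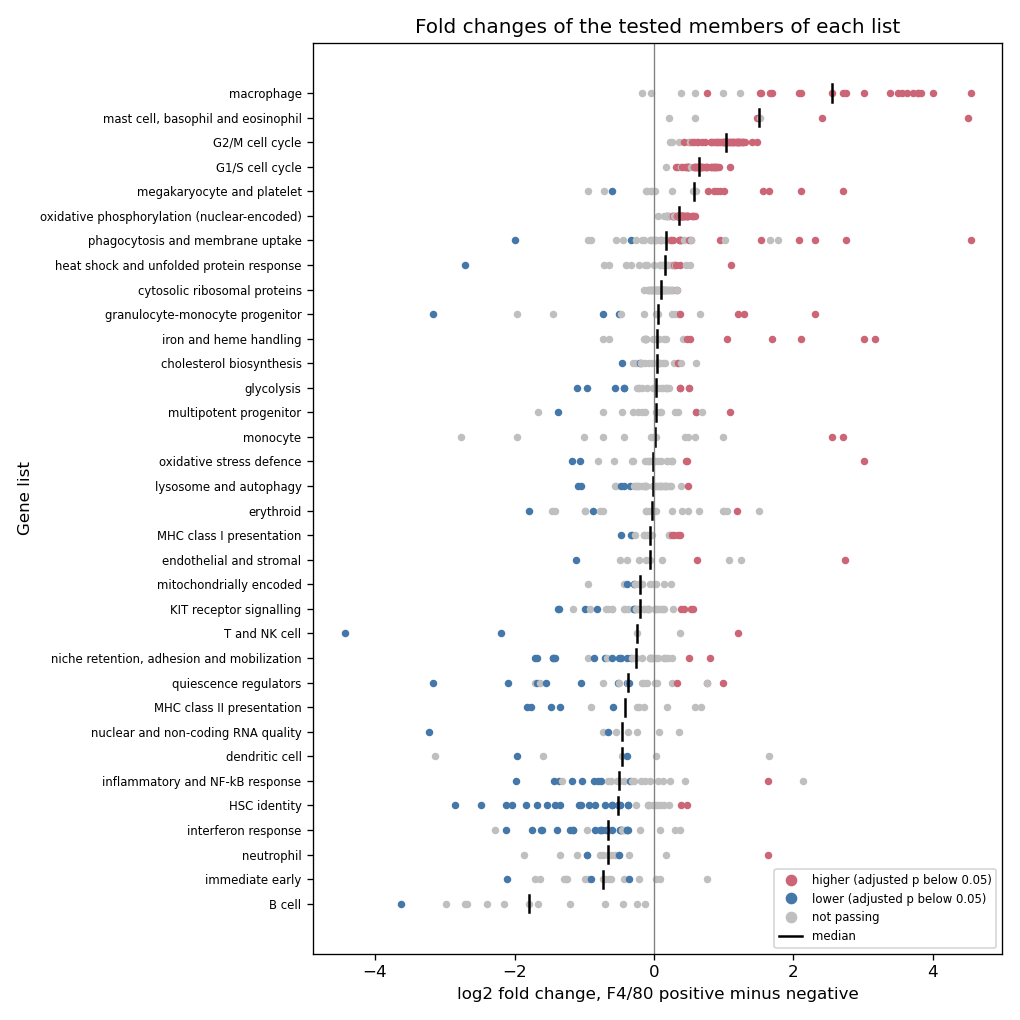
Log2 fold change, F4/80 positive minus negative, of every tested member of the 34 lists with at least 5 tested members. Each point is a gene, coloured where its edgeR adjusted p is below 0.05, and black bars are list medians. The macrophage list has the highest median at 2.55, and the B cell list the lowest at -1.80.

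**Figure D4:**
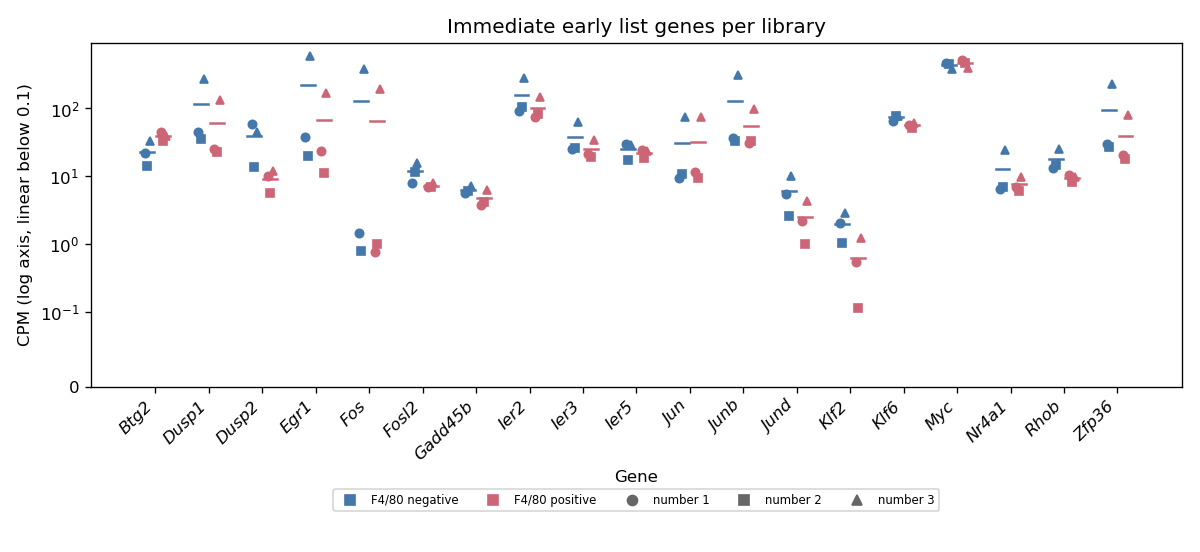
CPM of the 19 tested immediate early genes in each library, on a log axis that is linear below 0.1 CPM. Colours mark the groups, symbols the replicate numbers and lines the group means of 3 libraries. For Fos, named after its values were seen, the libraries numbered 3 lie at 382 and 191 CPM, and the other 4 between 0.75 and 1.46 CPM.

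The genes with the largest changes by the fixed rule were led by macrophage genes on the higher side. Besides those above they included Fcna, a ficolin, with 14.3-fold, the lectin Cd209f with 12.2-fold, Pilra with 10.6-fold and Siglec1 with 10.4-fold. Siglec1 lost its call with DESeq2 (adjusted p = 0.106) and limma-voom (adjusted p = 0.0719), and in edgeR without negative replicate 1, negative replicate 3, positive replicate 1 or positive replicate 2. Its adjusted p over the alternatives ranged from 0.0012 to 0.12. The fold of Siglec1 was 26.1 without negative replicate 2, and that of Pilra 17.7 without negative replicate 1. On the lower side were Neo1, which encodes the receptor neogenin, 20.3-fold lower, Cyp26b1, a retinoic acid-degrading enzyme, 19.5-fold, the GTPase genes Gbp4 18.6-fold and Gbp9 9.88-fold, and Gimap3 11.4-fold. Neo1 was 12.7-fold lower without negative replicate 3 and 41.8-fold lower without positive replicate 1, and Gbp4 37.5-fold lower without positive replicate 2. Jchain, the joining chain of secreted antibodies, measured 0.342 ± 0.216 CPM in positive and 47.5 ± 40.7 CPM in negative libraries (SD, n = 3). Negative replicate 3 lay near the positive libraries, with 0.821 CPM against 66.1 and 75.5 CPM in negative replicates 1 and 2. Jchain lost its call when any 1 positive library was left out and with limma-voom. Its adjusted p over the alternatives ranged from 2.35e-05 (DESeq2) to 0.371 (limma-voom).

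With the replicate block the immediate early list had 12 lower and 1 higher of 19 genes and was called by camera (adjusted p = 0.000957, against 0.124 without the block). The dendritic cell list then had 4 lower of 7 (camera adjusted p = 0.0394, against 0.177), and KIT receptor signalling 12 lower and 5 higher of 41 (camera adjusted p = 0.0282, against 0.124). Each of these 3 lists had adjusted p = 0.454 with an estimated correlation and the block. Without both libraries numbered 3, edgeR called 0 of the 19 immediate early genes (9 at an unadjusted p below 0.05). In lists whose camera result stayed on the same side, the block gave 7 lower B cell genes of 13, 6 higher mast cell, basophil and eosinophil genes of 6, and 20 higher and 6 lower uptake genes of 44. Inflammatory genes had 15 lower and 2 higher of 27, niche genes 18 lower and 5 higher of 34, iron and heme genes 8 higher and 2 lower of 23, and interferon genes 28 lower and 1 higher of 33. Megakaryocyte and platelet genes had 11 higher and 2 lower of 20, and MHC class II genes 5 lower and 1 higher of 12. Ribosomal protein genes had 10 higher of 55, heat shock genes 12 higher and 3 lower of 27, oxidative stress genes 7 higher and 6 lower of 24, and mitochondrially encoded genes 6 lower of 15. Erythroid genes had 3 higher and 6 lower of 22, multipotent progenitor genes 3 higher and 6 lower of 17, monocyte genes 2 higher and 2 lower of 15, and glycolysis genes 6 higher and 6 lower of 23. Lysosome and autophagy genes had 1 higher and 8 lower of 39, cholesterol biosynthesis genes 2 higher and 2 lower of 23, nuclear and non-coding RNA 4 lower of 8, and sex-linked genes 1 lower of 4.

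With the replicate number as a block, edgeR called 2105 genes higher and 2429 lower. With total counts and no composition factor 32.3% of the called genes were higher, against 47.0% with TMM factors. The counts were 750 higher and 812 lower without negative replicate 3, 824 and 841 without positive replicate 1, 723 and 907 without positive replicate 2, and 656 and 802 without positive replicate 3. None of the 16 list calls by camera with its preset correlation held with an estimated correlation (6 lists at an unadjusted p below 0.05). Fry called 14 of these 16 lists, all but B cell and ribosomal proteins, and also nuclear and non-coding RNA quality (fry adjusted p = 0.00109), which camera did not call (adjusted p = 0.124).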

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

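The fit without the libraries numbered 3, the length correction and the estimated correlation with the block were chosen after seeing the data. With the replicate block, which pairs the libraries, edgeR called 2105 genes higher and 2429 lower. With the block and the gene length correction it called 2337 higher, and 2162 lower. Without both libraries numbered 3, which leaves 2 against 2, 380 genes were higher and 413 lower, fewer libraries being tested. Over the fits that leave out 1 library, higher genes ranged from 656 to 1437, lower genes from 802 to 1612, lists called from 14 to 19 and the Adgre1 log2 fold change from 3.55 to 4.02. Camera called 0 lists with an estimated correlation, both without and with the block (6 and 2 lists at an unadjusted p below 0.05), and for each of the 16 lists called with the preset the estimate was larger than the preset. All other settings left both gene counts within 1.5 times. No result changed direction across a call. Among the 176 other named genes the block added 5 calls (Kit, Flt3, Cd79a, Hbb-bs and Sirpa) and ended none. Leaving out positive replicate 3 ended 44, and leaving out both libraries numbered 3 ended 64. With the block 3 more lists were called: dendritic cell, KIT receptor signalling and immediate early genes, each with adjusted p = 0.454 with an estimated correlation and the block. Total counts alone moved the median log2 fold change of all genes from -0.03 to -0.10 and ended 9 named calls and 2 list calls. DESeq2 gives no list test here. Depth sets a floor of 0.147 to 0.167 CPM for 3 counts. The causes of these shifts were not tested.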

Other observations

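The tests of macrophage, monocyte and eosinophil genes, of dilution, of megakaryocyte genes and of immediate early genes were chosen after their results were seen, and the length test and the splits of the libraries before. Immediate early genes, which cells switch on within minutes of a stimulus or of handling, set the libraries numbered 3 apart in both groups (genes named here were chosen after their values were seen). Fos measured 382 CPM in negative replicate 3 and 191 CPM in positive replicate 3, and between 0.75 and 1.46 CPM in the other 4 libraries. Junb measured 315 and 99.0 CPM against 30.8 to 37.2 CPM, and Jun 73.7 and 75.0 CPM against 9.37 to 11.6 CPM. Of the 21 higher macrophage genes 19 had their lowest level of the positive group in positive replicate 3, as did 22.6% of the 1374 other higher genes. The 2 exceptions were Apoe and Trem2.

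A candidate explanation for the macrophage transcripts is RNA from macrophages in the positive libraries, as whole cells attached to stem cells, as doublets, or as material taken up by them. The 21 higher and 0 lower of 27 macrophage genes are the pattern itself, so they carry no weight for it. Lyz2 was not higher, and Cd74 was lower, with 56.7 CPM in positive and 193 CPM in negative libraries. Negative libraries already held much of both transcripts (487 CPM of Lyz2), so neither gene decides. Monocytes or a broad myeloid program are argued against by the 10 monocyte genes outside the macrophage list, with a median log2 fold change of -0.21 (SD 1.06) against 2.55. Eosinophils, which also carry F4/80, stay open. Prg2 and Epx summed to only 1.08 CPM in the positive libraries, near the floor. The eosinophil receptor Ccr3 was higher there, with 26.2 ± 9.54 against 2.90 ± 0.354 CPM (SD, n = 3). The 3 higher genes of the mast cell, basophil and eosinophil list were Cpa3, Ms4a2 and Fcer1a, genes of mast cells and basophils. They do not bear on eosinophils, and Ms4a2 and Fcer1a lost their calls in 3 and 6 alternative settings. Bulk counts leave open whether macrophage RNA came with cells, fragments or expression by the stem cells themselves.

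For the lower stem cell genes with higher cell cycle genes, dilution by macrophage RNA would lower alike every identity gene that macrophages lack. Which identity genes macrophages lack was not checked. Of 33 identity genes 11 had a log2 fold change above -0.25, while 11 others lay below -1. This argues against dilution as the whole cause only so far as macrophages lack the first 11 genes. A gene length trend is argued against as the whole cause. In the fit with the block, 51 of 52 G2/M genes were higher both before and after its removal. The correlation of fold change with length across genes went from -0.15 to -0.004, which shows only that the trend was removed. A larger share of megakaryocyte-committed, dividing cells in the positive gate may contribute, since 9 megakaryocyte genes rose against 1 erythroid gene. Whether single stem cells changed or the mix of cells did remains open in bulk libraries.

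For the immediate early genes, handling or an animal shared by libraries of the same number is a candidate explanation. In 10 of 19 such genes both libraries numbered 3 lay above the other 4, against 1 gene for number 1 and 0 for number 2, and 6.67% expected with no structure. These counts are the pattern itself and do not test its cause. The labels give no sort day or animal, so handling and animal are both open. Without both libraries numbered 3, 2 against 2, edgeR called 20 macrophage, 41 G2/M and 22 of 42 G1/S genes higher. It called 11 of 33 identity and 10 of 33 interferon genes lower. It called 0 immediate early and 0 oxidative phosphorylation genes (9 of 19 and 34 of 52 at an unadjusted p below 0.05). The median log2 fold change of oxidative phosphorylation genes was then 0.30, against 0.36 with all libraries, so the lost calls do not mean a lost change. For immediate early genes it was -0.38 against -0.73, for identity genes -0.55 against -0.52, and for interferon genes -0.59 against -0.66.

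The 6 libraries form 10 splits of 3 against 3, too few for a share below 0.05. The real split gave 1395 higher and 1572 lower genes in edgeR and was 1 of 10 to reach that many, while the highest other split gave 0 genes (91 to 941 at an unadjusted p below 0.05, against 5179). The same held among the 4 splits that part all 3 pairs. For lists called by camera with the preset correlation, 3 of the 10 splits gave at least the real 16, with 18 the highest other and 13 the highest other among those that part all pairs. Fry called 15 lists in the real split and at most 1 in the others. Each other split sets 2 libraries of 1 group with 1 of the other against the reverse mix, so it still holds part of the group difference and is no measure of calls without one.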
